A study of Homo sapiens with 17 samples.

How the data were processed

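Gene expression was measured by RNA sequencing in 17 libraries, each from CD138-selected bone marrow cells of a person with multiple myeloma. CD138, the product of SDC1, is a surface marker of plasma cells, and the selection enriches the tumour cells of this disease. Per the labels' protocols, CD138-positive cells were selected on a RoboSep instrument, polyadenylated RNA was made into TruSeq libraries, and these were sequenced as read pairs on a HiSeq2500. The labels place every library at the baseline of a trial that combined pomalidomide with cyclophosphamide and dexamethasone in relapsed or refractory disease. They give no response, dose or later time point, so the 17 libraries form a single group and no comparison between groups was made.

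The deposited sample files hold raw counts of read pairs per gene. Per the file headers they were made with featureCounts 1.5.1 over the exons of Ensembl release 75, from sorted alignments with marked duplicates. The options recorded in the headers set no strand, no counting of multi-mapping reads, no counting of reads over overlapping genes and no removal of duplicates. The submitters' processing notes name STAR 2.5, featureCounts, Subread 1.5.1, DESeq2 and GRCh37. Reads from a gene and from an antisense partner cannot be told apart in such counts, and a read over exons of several genes was left uncounted. Among genes with a count, 1467 have under 50% of their exonic bases to themselves, and levels of such genes are lower bounds. The deposited table of the whole series is named as counts, but its values are on a log2 scale with a floor of 1.38, and the authors' log2 values were therefore used as they are and only as an alternative. The alternative had been planned as log2 of the deposited value plus 1, and this step was dropped. All coordinates are those of the count files, on GRCh37.

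The files hold 63677 Ensembl identifiers, of which 52181 were matched to a symbol, and the matched ones carry 98.4% of the counts. Symbols and biotypes came from GENCODE v29 and NCBI RefSeq name tables, and no coordinates were taken from them. Genes of chromosome Y, XIST and TSIX were kept in the library totals and left out of every test. TXNIP, BOP1 and CD24 matched only identifiers on patch sequences, which held no counts, and PSMB3 matched none by the name tables, so no values are given for these 4 genes. Of 381 entries in the 28 gene lists, 371 were kept.

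Counts were normalized with the trimmed mean of M values (TMM) in edgeR 4.0.16 and are given per 1e+06 normalized counts (CPM). Length-normalized values (TPM, transcripts per 1e+06 transcripts) were computed from the counts and the gene lengths in the files. These lengths cover all annotated exons of a gene, not the transcript expressed. In a gene pair they act as a nearly constant offset, which the test of pairs does not address. Genes with at least 10 counts in at least 3 libraries were tested, 21515 in all. Spread was tested with edgeR's robust quasi-likelihood fit of an intercept, setting each gene's quasi-dispersion against the abundance trend by an F test in each tail. Associations with the log2 CPM of CRBN, and with a proliferation score, used edgeR's quasi-likelihood test with that value as a covariate. Slopes are in log2 units of the gene per log2 unit of the covariate. CRBN itself was left out of the former, and the score's own genes out of the latter. Gene lists were tested along each covariate with camera, at its preset correlation and at an estimated one. A score is the mean over a list's kept genes of log2 CPM (prior count 2), each centred on its own mean.

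Co-variation of a list is the mean pairwise Spearman correlation of its members over libraries, set against 10000 random lists of the same size matched on mean expression in 20 bins, in a one-sided test. Relations across libraries are Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples. Genes within a library were compared on log2(TPM + 1) by a two-sided permutation test that swaps both genes within libraries, also with 100000 resamples. The smallest p these can give are 0.0001 for lists and 1e-05 for relations and gene pairs. P-values were adjusted by Benjamini-Hochberg within their family at 0.05. For relations the adjustment was made on the p of rho only, and the p of r is given unadjusted. The families held 28 lists, 21 relations and 15 pairs.

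The sample files' names end in codes that recur between libraries, and the meaning of these codes is not given. There are 7 codes, and 6 of them are shared by 2 to 5 libraries, 16 libraries in all. Genes that differ among the shared codes were tested as a check, and a code term or values centred within codes served as an alternative. No code holds 6 libraries, so no correlation was computed within a single code.

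Tests, gene lists, pairs, relations, alternatives and the rule for named genes were fixed before the data were examined. The rule named CRBN, IKZF1, IKZF3, IRF4, MYC, NR3C1, the genes of the pairs and relations, and in each list the 2 kept genes with the highest mean CPM and the 2 with the largest spread ratio. It further named the 25 most variable protein-coding genes with at least 3 libraries lying 2 or more log2 units from the median, the 10 least variable with a mean of at least 20 CPM, and the 15 smallest p in each direction along a covariate. Immunoglobulin and T cell receptor segments and genes with common whole-gene deletions were not to be named, and a few genes that the rule names are not reported here. No gene passed the spread test, so its part of the rule was applied without the threshold, a choice made after the data were seen. Genes named because they passed within their list alone, or because low counts kept them out, were also chosen after their values were seen. Placing each list's spread among random lists was also added then.

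Alternatives were RLE size factors, TMM without immunoglobulin genes, edgeR's filterByExpr, no filter, a code term, leaving out the library with the fewest counts or with the most markers of other cells, limma-trend, a non-robust prior, DESeq2, prior counts of 0.5 and 5, a pseudocount of 0.1, CPM without gene length, Pearson correlation and the authors' values. The tools were R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

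The tests of spread, slopes and codes were tried on simulated data, with 200 genes changed among counts drawn from the real means and library sizes. Those of co-variation and relations were tried on shuffled genes, and camera and the gene pairs were not tried in this way. With gene-to-gene heterogeneity of the dispersion added, the spread test recovered 0 of 81 genes given 10 times the dispersion, with 0 false calls. It recovered 33 of 97 given 0.1 times, with 8 false calls, on the same 20236 genes. Without that heterogeneity it recovered 99 of 99 and 74 of 95, on 20609 genes, with 0 and 6 false calls. The dispersions were also capped in that run, below the common dispersion of 1.035 of these data. Its higher recovery cannot be credited to the lack of heterogeneity alone. Along CRBN, 0 of 94 genes with a slope of 1 and 44 of 96 with a slope of 3 were recovered on 20307 genes, with 4 false calls. Along the proliferation score these were 3 of 100 and 65 of 96 on 20309 genes, with 3 false calls. For a log2 difference of 4 in a single code, 8 of 95 genes were recovered on 20170 genes, and for one of 2 it was 0 of 94, with 0 false calls. The heterogeneity added in the spread, slope and code runs was fitted to the quasi-dispersion but applied to the dispersion of the counts. It raised the simulated dispersions above the fitted trend on average. The recoveries in those runs may therefore differ from those in the real data. The list test called 1 of 1 list with a shared factor and 0 of 27 lists of shuffled genes, and 0 of 21 relations among shuffled genes passed.

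Library totals ranged from 26.5 M to 83.4 M counts with a median of 54.7 M, where M stands for 1e+06. After TMM the library sizes ranged from 19.76 M to 101.3 M, so 1 CPM stands for about 19.76 counts or more in every library. Pairwise Pearson correlations of log2 CPM ranged from 0.883 to 0.968, and no library was a copy of another.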

Results

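RNA sequencing counts were available for 17 libraries of CD138-selected bone marrow cells, all taken at baseline from people with relapsed or refractory multiple myeloma. The labels give each library as from a separate patient. Total counts ranged from 26.5 M to 83.4 M (median 54.7 M), and 18728 to 29151 genes had at least 1 count (median 26398). Immunoglobulin genes took 22.9% of counts in the median library, with a range from 8.89% to 53.4%. Mitochondrial genes took 3.36% in the median library, with a range from 1.35% to 20.8%. The design holds a single group, so the values below describe levels, their spread between tumours, and relations within and across the libraries.

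The trial's drugs are pomalidomide, which acts through cereblon, cyclophosphamide, an alkylating prodrug, and dexamethasone, a ligand of the glucocorticoid receptor. The first question was therefore how these tumours expressed the genes on which the drugs act. CRBN, which encodes cereblon (ENSG00000113851, chromosome 3, 3190676 to 3221394, GRCh37), had a median of 24.1 CPM with quartiles of 19.6 and 31.7 and a mean of 24.4 ± 8.38 (SD, n = 17). IKZF1 (ENSG00000185811, chromosome 7, 50343720 to 50472799) and IKZF3 (ENSG00000161405, chromosome 17, 37921198 to 38020441) encode Ikaros and Aiolos, the transcription factors that cereblon degrades in the presence of pomalidomide. IKZF1 had a median of 111.6 CPM (quartiles 70.6 and 138.5) and IKZF3 a median of 28.1 CPM (quartiles 21.6 and 41.4). Their target IRF4 (ENSG00000137265, chromosome 6, 391739 to 411447), a transcription factor on which myeloma cells depend, had a median of 549.1 CPM. MYC (ENSG00000136997, chromosome 8, 128747680 to 128753674) had a median of 258.8 CPM and ranged from 66.8 to 660.3 CPM. NR3C1, the glucocorticoid receptor gene (ENSG00000113580, chromosome 5, 142657496 to 142815077), had a median of 76.9 CPM and ranged from 15.3 to 290.0 CPM.

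**Figure D1:**
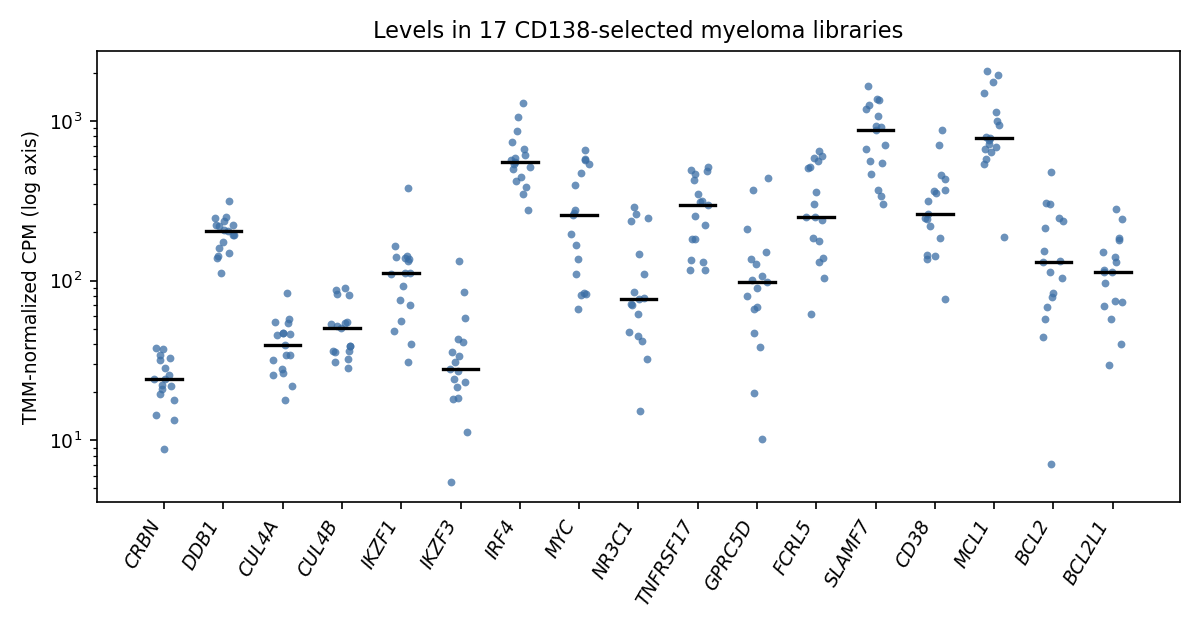
TMM-normalized CPM (log axis) of 17 genes, each point a library (n = 17) and each bar the median. SLAMF7 and MCL1 have the highest medians, 870.0 and 786.2 CPM, and CRBN the lowest, 24.1 CPM.

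Below, the highest genes of a list are those with the highest mean CPM, and those that varied most are those with the largest ratio of spread to the trend of genes of like abundance. All 20 genes of the cereblon ligase list, the E3 ubiquitin ligase and its regulators, were kept for testing. DDB1, the adaptor that binds cereblon, was the highest with UBE2D3, at medians of 203.6 and 188.7 CPM. UBE2G1 and COPS2 varied most in this list, with SDs of 0.72 and 0.64 log2 units. Within libraries, CRBN lay below DDB1 by a mean of -1.91 log2(TPM + 1) units (SD 0.466, n = 17), lower in 17 of 17 libraries (two-sided permutation test, p = 3e-05, adjusted p = 6.43e-05), and by -3.02 without division by gene length (adjusted p = 7.5e-05). CUL4A and CUL4B, the alternative scaffold subunits, differed by a mean of -0.06 (SD 0.756), with CUL4A higher in 9 of 17 libraries (adjusted p = 0.788), and by -0.34 without gene length (adjusted p = 0.132). IKZF3 and IKZF1 differed by 0.06 (SD 1.13), with IKZF3 higher in 9 of 17 libraries (adjusted p = 0.820). Without division by gene length, IKZF3 lay below IKZF1 by -1.70 (adjusted p = 0.00035). In the neosubstrate list, the proteins recruited to cereblon by this class of drugs, IKZF1 and CSNK1A1 were highest, the latter at 78.3 CPM with 49.9% of its exonic bases unique. ZNF692 and ZNF276 varied most, with SDs of 1.20 and 1.16 log2 units.

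Genes tied to the other drugs were unevenly expressed. In the glucocorticoid response list, TSC22D3, which encodes GILZ, had a median of 400.6 CPM. ANXA1, the annexin A1 gene, had a median of 11.3 CPM but ranged from 0.373 to 1066 CPM, and DDIT4 had a median of 62.4 CPM. NR3C1 exceeded NR3C2, the mineralocorticoid receptor gene, by 3.58 log2(TPM + 1) units (SD 1.24) in 17 of 17 libraries (permutation test, adjusted p = 6.43e-05), and by 5.42 with a pseudocount of 0.1. Of 14 cyclophosphamide metabolism genes, 9 were kept. Among those left out for low counts, the cytochrome genes CYP2B6 and CYP2C19, and ALDH3A1 and GSTA1, had a median of 0 CPM. GSTP1 and GGT1, glutathione pathway genes, had medians of 174.6 and 33.6 CPM, and ABCC4 ranged from 0.110 to 71.9 CPM. Among efflux transporters, ABCC1 and MVP were highest at 47.9 and 101.7 CPM. ABCB1, the multidrug transporter gene, had a median of 0.682 CPM, and ABCC1 exceeded it by 3.12 log2(TPM + 1) units (SD 0.600) in 17 of 17 libraries (adjusted p = 6.43e-05), and by 4.985 with a pseudocount of 0.1. ABCG2 ranged from 0 to 79.0 CPM and ABCC3 from 0.0414 to 228.2 CPM.

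Plasma cell identity genes had medians from 29.16 CPM for CD27 to 14690 CPM for JCHAIN, the immunoglobulin joining chain gene, which had quartiles of 2409 and 36080. XBP1, the secretory transcription factor, had a median of 1918 CPM and SDC1 a median of 1155 CPM. CD27 and TNFRSF13B varied most in this list, with SDs of 2.83 and 1.95 log2 units. Among surface antigens used for immunotherapy, TNFRSF17, which encodes BCMA, was compared with others in the same library. It exceeded GPRC5D by 1.55 log2(TPM + 1) units (SD 1.05), in 15 of 17 libraries (permutation test, adjusted p = 0.000112). It exceeded FCRL5 by 3.38 (SD 1.12), in 17 of 17 libraries (adjusted p = 6.43e-05). The difference from SLAMF7 was 0.49 (SD 0.708), in 13 of 17 libraries (adjusted p = 0.0145). Without division by gene length these became -0.05 (adjusted p = 0.86) for FCRL5 and -1.54 (adjusted p = 7.5e-05) for SLAMF7. SLAMF7 exceeded CD38 by 2.03 (SD 0.834), in 17 of 17 libraries (adjusted p = 6.43e-05). The B cell antigen gene MS4A1 had a median of 2.16 CPM.

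Survival and cell cycle genes were compared in the same way. MCL1 exceeded BCL2 by 3.64 log2(TPM + 1) units (SD 1.42) and BCL2L1 by 2.64 (SD 1.18), each in 17 of 17 libraries (permutation test, adjusted p = 6.43e-05 for both). BCL2 lay below BCL2L1 by -0.999 (SD 1.05) and was lower in 14 of 17 libraries (adjusted p = 0.00243). Without division by gene length that difference was 0.16 (adjusted p = 0.59). BCL2 ranged from 7.12 to 476.1 CPM. PMAIP1 and HRK, genes of pro-apoptotic members, varied most in this family, with SDs of 3.25 and 2.92 log2 units. CCND2 did not pass against CCND1 (mean -1.60, SD 4.97, adjusted p = 0.233) or CCND3 (mean -1.60, SD 3.65, adjusted p = 0.114), and it was the lower gene in 12 of 17 libraries in both pairs. PSMB5, a constitutive proteasome subunit gene, lay below its immunoproteasome relative PSMB8 by -0.53 (SD 0.650), lower in 14 of 17 libraries (adjusted p = 0.00385). In all, 11 of 15 pairs passed.

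The next question was which genes varied more or less between tumours than genes of like abundance. In edgeR's F test against the abundance trend, 0 of 21515 genes had more spread and 0 had less at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1235 with more and 1192 with less. Limma-trend and the non-robust prior also gave 0 in each direction, and without a filter on low counts 939 had more and 12 had less. The prior degrees of freedom were 3.87. With heterogeneity drawn at that value, the simulated test recovered 0 of 81 genes given 10 times the dispersion and 33 of 97 given 0.1 times. There were 8 false calls of less spread, and the simulated dispersions lay above the fitted trend on average. As none passed, the following genes are ranked, not called. The 25 at the top of the ranking were PDIA2, FGFR3, RND3, CLSTN2, NTRK2, BAMBI, TMPRSS11E, ISLR, CGREF1, WSCD1, EDNRB, MAF, UCHL1, CAVIN2, EEF1A2, ELANE, EPX, PPBP, PODXL2, AZGP1, F13A1, MACROD2, PF4, FMR1NB and PXDN. Their ratios of spread to trend ran from 51.6 for PDIA2 to 34.0 for PXDN. Such a rank may rest on few libraries. NTRK2, RND3, EEF1A2 and FMR1NB had upper quartiles of 3.42, 2.09, 0.325 and 0.108 CPM. Their maxima were 956.1, 638.0, 188.5 and 163.4 CPM. PODXL2 and AZGP1 were less uneven, with upper quartiles of 55.2 and 44.6 CPM and maxima of 174.3 and 191.6 CPM. FGFR3, a receptor tyrosine kinase gene activated by a recurrent translocation in myeloma, had a median of 0.676 CPM and ranged from 0.234 to 8880 CPM. MAF, a transcription factor gene likewise placed beside immunoglobulin enhancers in some myelomas, had a median of 5.50 CPM and ranged from 0 to 1065 CPM. ELANE and EPX encode granule proteins of neutrophil precursors and eosinophils, and PPBP, PF4 and F13A1 are abundant in platelets. The 10 at the bottom were UBTF, SF1, SUPT6H, PSMA7, RER1, TBC1D10B, ZNF384, LRRC47, IK and PPP4C. UBTF, which encodes a factor for ribosomal RNA transcription, had 94.95 CPM in the median library with an SD of 0.21 log2 units, and the ratios of these 10 ran from 0.128 to 0.174.

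Gene lists differed in spread. The median SD of log2 CPM was 3.01 in the cyclin D and translocation target list, 2.28 in class II presentation, 1.77 in the interferon response, 1.57 in the immediate early and stress genes and 1.21 in the NF-kappaB pathway. Each lay at or above the 99.99th percentile of random lists matched on expression, a description of these libraries and not a test. Lists tied to the drugs had median SDs of 1.38 for efflux transporters, 1.32 for the glucocorticoid response, 1.285 for cyclophosphamide metabolism and 0.76 for neosubstrates, at the 88.52, 99.97, 93.61 and 71.2 percentiles. Immunotherapy antigens had 1.01, plasma cell identity 0.87 and the BCL2 family 0.85, at the 99.37, 99.6 and 88.77 percentiles. CCND2 ranged from 0.454 to 2573 CPM, CCND1 from 0.296 to 1151 CPM and CCND3 from 15.6 to 965.7 CPM. In the interferon list, MX1 and IFI6 were highest with medians of 104.9 and 67.7 CPM, and RSAD2 and IFI27 varied most with SDs of 2.76 and 3.29 log2 units. In class II presentation, CD74 and CTSS had medians of 949.7 and 396.4 CPM, while HLA-DRA and HLA-DPA1 had SDs of 2.42 and 2.34. FOS and JUN led the immediate early list at 666.0 and 852.1 CPM, and EGR1 and NR4A1 varied most, with SDs of 2.25 and 2.37. In the NF-kappaB list NFKBIA and BIRC3 were highest at 100.4 and 113.0 CPM, and BIRC3 and TNFAIP3 varied most, with SDs of 3.15 and 1.75. The proteasome, cereblon ligase and oxidative phosphorylation lists lay low, at the 0.15, 3.79 and 1.99 percentiles, with median SDs of 0.50, 0.54 and 0.51.

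Other tumour programmes had median SDs of 0.89 for proliferation, 0.82 for hypoxia and glycolysis, 0.73 for the unfolded protein response, 0.70 for MYC targets, 0.67 for ribosomal proteins and 0.58 for the immunoproteasome and class I presentation. HSPA5 and HSP90B1, chaperones of the endoplasmic reticulum, had medians of 2014 and 2296 CPM, and HERPUD1 and MANF varied most in the unfolded protein response list with SDs of 1.07 and 0.90. PSMB4 and PSMD2 led the proteasome list at 173.6 and 160.5 CPM, and PSMA6 and PSMD7 had its largest ratios. B2M, the light chain of class I molecules, had a median of 7432 CPM and TAPBP 482.5 CPM, and PSMB10 and NLRC5 varied most beside them. NPM1 and NCL led the MYC targets at 480.7 and 453.7 CPM, and NOP16 and NME1 had SDs of 0.95 and 0.89. RRM2 and TOP2A led the proliferation list at 83.1 and 43.7 CPM, and ASPM varied most with an SD of 1.28. RPL3 and RPL4 led the ribosomal proteins at 2741 and 2776 CPM, and RPS2 and RPS18 had SDs of 0.87 and 0.92. ATP5F1A and ATP5F1B led oxidative phosphorylation at 401.1 and 340.6 CPM, and NDUFA4 and COX4I1 varied most. ENO1 and ALDOA led the hypoxia and glycolysis list at 358.1 and 424.5 CPM, while SLC2A1 and ADM had SDs of 1.12 and 2.49.

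Markers of other cell types were present in the selected samples and varied between them. LYZ and S100A9, abundant in monocytes, had medians of 27.5 and 43.9 CPM and reached 1473 and 1793 CPM, and VCAN and MNDA had SDs of 3.03 and 3.41. MPO, ELANE and PRTN3 of granulocyte precursors had medians of 15.3, 6.01 and 5.83 CPM. The haemoglobin genes HBB, HBA2 and HBA1 had medians of 216.4, 29.9 and 4.42 CPM, the last 2 being uncertain as near-identical copies whose shared reads were not counted, and SLC4A1 had an SD of 2.79. PPBP, PF4 and TUBB1 of platelets had medians of 7.59, 4.27 and 5.98 CPM. CD3E, NKG7 and IL7R of T and NK cells had medians of 6.72, 3.32 and 1.68 CPM. PAX5 of B cells had a median of 13.7 CPM. CXCL12, LEPR and COL1A2 of stromal cells had medians of 66.3, 10.4 and 4.39 CPM. These genes were named for high levels or large spread in their lists. Over all kept genes of a list, the median of their median CPM was 7.88 for monocyte, 7.51 for erythroid and 5.13 for megakaryocyte markers. It was 5.04 for granulocyte precursor, 4.60 for stromal, 1.88 for B cell and 1.115 for T and NK markers. Median SDs of these 7 lists ran from 2.05 for stromal to 2.996 for megakaryocyte and platelet markers.

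Most lists varied together over the 17 libraries: 20 of 28 passed against random lists. Outside the cell type markers, the mean pairwise rho was highest for ribosomal proteins at 0.752, class II presentation at 0.717, proliferation at 0.684 and the interferon response at 0.576 (adjusted p = 0.000187 for each). MYC targets had 0.419, immediate early and stress genes 0.374, oxidative phosphorylation 0.355, unfolded protein response and secretion 0.317 and the proteasome 0.260 (adjusted p = 0.000187 for each). The NF-kappaB pathway had 0.297 (adjusted p = 0.00035), immunoproteasome and class I presentation 0.181 (adjusted p = 0.0275), plasma cell identity 0.169 (adjusted p = 0.032) and the cyclin D and translocation targets 0.120 (adjusted p = 0.0483). The last lost its call in 8 alternatives and plasma cell identity in 3. Cell type markers gave 0.892 for monocytes, 0.854 for erythroid cells, 0.851 for megakaryocytes and platelets, 0.836 for granulocyte precursors, 0.687 for stroma and 0.567 for T and NK cells (adjusted p = 0.000187 for each), and 0.341 for B cells (adjusted p = 0.00181). Of the lists tied to the drugs none passed: the cereblon ligase list had 0.08 (adjusted p = 0.0664), glucocorticoid response 0.04 (0.259), neosubstrates 0.03 (0.259), efflux transporters 0.03 (0.269) and cyclophosphamide metabolism 0.00 (0.412). Immunotherapy antigens (0.10, adjusted p = 0.089), hypoxia and glycolysis (0.08, adjusted p = 0.107) and the BCL2 family (0.06, adjusted p = 0.0951) did not pass either. Centred within file-name codes, 4 of these 8 lists passed: the cereblon ligase list at 0.132 (adjusted p = 0.00192), hypoxia and glycolysis at 0.215 (0.00156), the BCL2 family at 0.108 (0.0179) and immunotherapy antigens at 0.107 (0.0408). The cereblon ligase list also passed without the library with the fewest counts (0.0854, adjusted p = 0.0284), and hypoxia and glycolysis with the authors' values (0.0959, adjusted p = 0.0269).

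**Figure D2:**
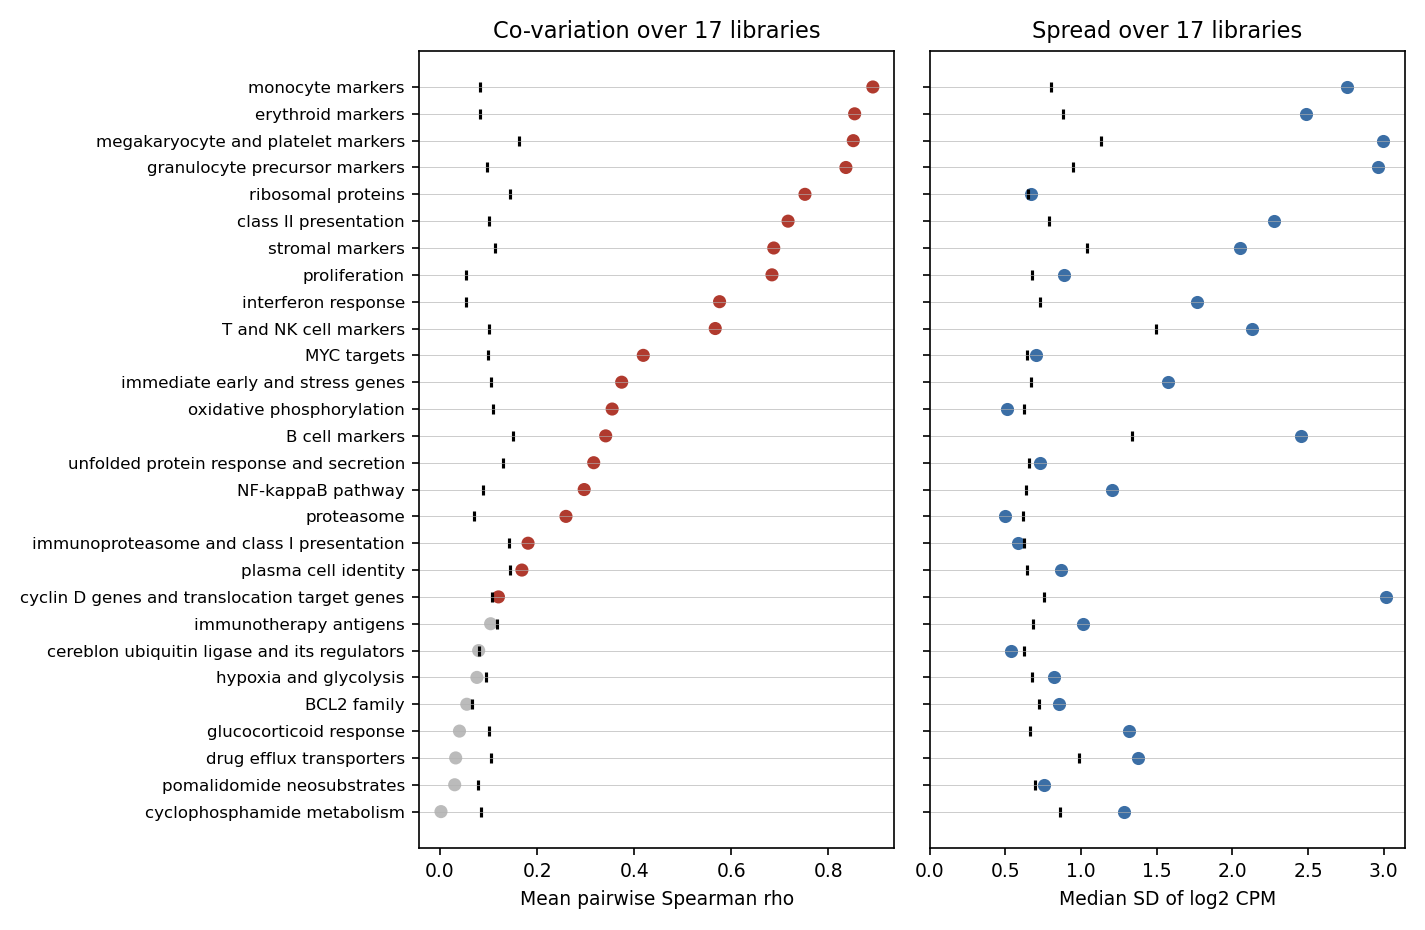
Mean pairwise Spearman rho (left) and median SD of log2 CPM (right) of the 28 gene lists over 17 libraries. Red points passed the test, grey points did not, and black ticks mark the 95th percentile (left) or the median (right) of 10000 matched random lists; monocyte markers have the highest rho, 0.892.

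Of 21 relations across libraries, 4 passed on rho, the only statistic whose p was adjusted. MYC was higher where its target genes were higher, with rho = 0.750 and r = 0.745 (permutation p = 0.00092 and 0.00089, adjusted p = 0.00644), and r was 0.633 without the 2 libraries farthest from the median of MYC. The class II score rose with the monocyte score, with rho = 0.843 and r = 0.851 (p = 5e-05 and 2e-05, adjusted p = 0.00105, r = 0.758 without 2 libraries). The monocyte and the T and NK scores rose together, with rho = 0.794 and r = 0.738 (p = 0.00022 and 0.00083, adjusted p = 0.00231, r = 0.853 without 2). The erythroid and granulocyte precursor scores did as well, with rho = 0.699 and r = 0.818 (p = 0.00249 and 5e-05, adjusted p = 0.0131, r = 0.617 without 2). Centred within file-name codes over 16 libraries, rho was 0.350, 0.521, 0.612 and 0.627 in that order, and 0 of 21 relations passed (adjusted p = 0.437, 0.355, 0.233 and 0.355).

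**Figure D3:**
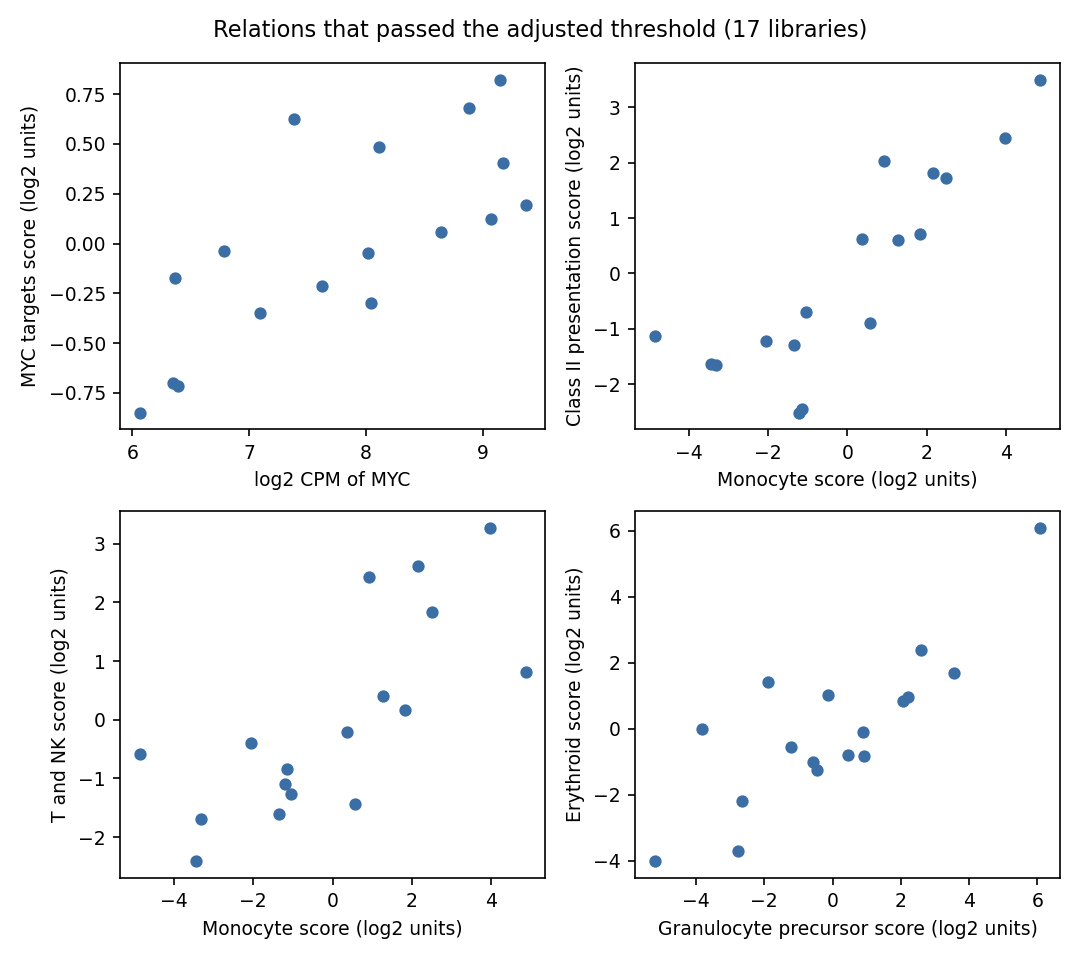
The 4 relations that passed, each point a library (n = 17). The axes show log2 CPM of MYC, or scores in log2 units (mean centred log2 CPM of a list's genes); rho is 0.750 for MYC and its targets, 0.843 for monocyte and class II, 0.794 for monocyte and T and NK, and 0.699 for granulocyte precursor and erythroid scores.

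The relations between genes of the pomalidomide pathway did not pass. CRBN against IKZF1 had rho = 0.427 and r = 0.533 (p = 0.0908 and 0.028, adjusted p = 0.23), and r fell to 0.284 without the 2 outermost libraries. CRBN against IKZF3 had rho = -0.06 and r = 0.254 (p = 0.819 and 0.325, adjusted p = 0.906), and r turned to -0.304 without the 2 outermost libraries. IRF4 had rho = 0.039 with IKZF1 (adjusted p = 0.927), 0.375 with IKZF3 (adjusted p = 0.266) and 0.321 with MYC (adjusted p = 0.366), and r was 0.255, 0.391 and 0.269 (p = 0.321, 0.119 and 0.298), the first turning to -0.069 without the 2 outermost libraries. NR3C1 against the glucocorticoid response score had rho = -0.22 and r = -0.20 (p = 0.393 and 0.441, adjusted p = 0.551). XBP1 against the unfolded protein response had rho = 0.549 and r = 0.511 (p = 0.024 and 0.0349, adjusted p = 0.084), and the proteasome against oxidative phosphorylation had rho = 0.507 and r = 0.645 (p = 0.0393 and 0.00465, adjusted p = 0.118). The immediate early and NF-kappaB scores had rho = 0.586 and r = 0.446 (p = 0.0147 and 0.077, adjusted p = 0.0619). Proliferation had rho = 0.404 with MYC targets, -0.40 with plasma cell identity and -0.12 with oxidative phosphorylation (adjusted p = 0.23, 0.23 and 0.761), and r was 0.379, -0.484 and -0.0271 (p = 0.134, 0.0478 and 0.918). The unfolded protein response had rho = 0.267 and r = 0.361 with the proteasome (p = 0.301 and 0.154, adjusted p = 0.451). The interferon score had rho = 0.294 with the immunoproteasome and -0.14 with monocyte markers (adjusted p = 0.405 and 0.725), and r was 0.344 and -0.117 (p = 0.178 and 0.655). Plasma cell identity had rho = 0.022 with monocyte and 0.154 with T and NK markers (adjusted p = 0.936 and 0.725), and r was 0.0303 and 0.140 (p = 0.907 and 0.592).

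Expression along CRBN was examined because cereblon is the direct target of pomalidomide. At an adjusted p of 0.05, 10 genes were associated with CRBN, 2 positively and 8 negatively (edgeR quasi-likelihood test, n = 17). The positive genes were FIBIN, with a slope of 14.6 ± 2.08 (SE, adjusted p = 0.0179), and BMP6, a growth factor gene, with a slope of 1.83 ± 0.327 (adjusted p = 0.0479). FIBIN had a mean of 4.825 CPM, and log2 CPM of CRBN ran only from 3.14 to 5.24. The slope of FIBIN may therefore rest on few libraries. The negative genes included MIR142HG, the host gene of a blood cell microRNA (slope -2.57 ± 0.334, adjusted p = 0.00676), SERPINF1 (-3.02 ± 0.449, adjusted p = 0.0179), MSTO1 (-1.19), CRABP2 (-2.19), SLC9A5 (-2.37) and CLSTN3 (-0.92). The other 2 were antisense genes without a symbol, and for them and MIR142HG reads of the opposite strand cannot be told apart. DESeq2 called 509 genes, and edgeR gave 2820 with an unadjusted p under 0.05. None of the 10 calls is firm: 0 genes passed without the library with the fewest counts, with the file-name code as a term, or without the 2 libraries farthest from the median of CRBN. Below the threshold, the next genes by p were INSR, NDST1, MAP3K7CL, LINC02315, NCK2, STK24, PIP5K1B, KIAA1191, SNX29, CHMP3, ILRUN, RGP1 and MTURN with positive slopes and adjusted p from 0.0832 to 0.126. With negative slopes they included COL6A4P2, ACTG1P17, SAPCD1, GBAP1 and EYA1, with adjusted p from 0.0509 to 0.0578.

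No list member passed along CRBN over all genes tested. Adjusted over the list alone, 5 of 12 neosubstrate genes passed: IKZF1, ZFP91 and CSNK1A1 with slopes of 0.87, 0.77 and 0.71, and ZNF692 and ZNF276 with slopes of -1.28 and -1.17. Each list was adjusted separately, and 2820 of all 21514 genes had an unadjusted p under 0.05. The neosubstrate list as a set was not called by camera (adjusted p = 0.263, and 0.790 with the estimated correlation). The relation of CRBN to IKZF1 itself did not pass (rho = 0.427, adjusted p = 0.23), and its rho was -0.0235 within codes. As many as 10 genes passed over all genes tested in 12 of 101 orders of the libraries, the real one included. Of the 6 megakaryocyte and platelet markers, 5 passed adjusted over the list alone, all with positive slopes, among them TUBB1 at 3.71 ± 1.03. The same adjustment passed CCND3 with a slope of 2.06 and NSD2 and FGFR3 with slopes of -1.38 and -9.19. It also passed ABCC3, TRAF3 and NDRG1 with positive slopes, and AURKB, NOP56 and NME1 with negative ones. FGFR3 had a median of 0.676 CPM, an upper quartile of 5.35 and a maximum of 8880 CPM, so its slope may rest on few libraries. Camera at its preset correlation called 4 of 28 lists, all upward: monocyte markers and ribosomal proteins (adjusted p = 0.00198 for both), and NF-kappaB and megakaryocyte markers (adjusted p = 0.00867 for both). With an estimated correlation, 0 of 28 passed, and these 4 each had an adjusted p = 0.79. Median slope and test differed in sign for cyclophosphamide metabolism, efflux transporters, unfolded protein response, hypoxia, granulocyte and stromal lists, none of them called. Along CRBN, positive slopes were 6 of 6 for megakaryocyte, 9 of 11 for monocyte, 4 of 7 for B cell and 2 of 8 for stromal markers. They were 1 of 10 for granulocyte precursor, 0 of 10 for erythroid and 0 of 14 for T and NK markers. The CRBN values were not corrected for other cells, so slopes along CRBN need not be relations within tumour cells.

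Along the proliferation score, 155 genes were associated, 139 positively and 16 negatively, not counting the score's 23 genes (edgeR quasi-likelihood test, n = 17). The 15 smallest p among positive slopes belonged to GTSE1, KIF14, DLGAP5, NUF2, NCAPG, KIF23, ATAD2, KIF20A, CDCA8, DSCC1, TTK, SPAG5, MELK, CENPF and LINC01610. DLGAP5, a spindle assembly gene, had a slope of 1.42 ± 0.184 (SE, adjusted p = 0.00205), and CENPF, a kinetochore gene, had 1.17 ± 0.177 (adjusted p = 0.00345). Among negative slopes the smallest p belonged to SLC6A15, MARCKSL1, PRNP, MT1E, C1R, APLP1, EMILIN1, MAGEH1, EMP2, LGI4, EIF4G3, SFRP1, FBXW7 and ADCY2. The other 2 negative genes were among those not to be named. CCDC85C, the last of the 15 smallest p among genes that could be named, had an adjusted p = 0.0504. FBXW7, which encodes a ubiquitin ligase subunit that targets cyclin E and MYC, had a slope of -0.86 ± 0.198 (adjusted p = 0.0483). PRNP had -0.99 ± 0.197 (adjusted p = 0.0222). With the file-name code as a term 28 genes passed, 24 of them shared with the 155, and DESeq2 called 921, of which 145 were shared. Without the 2 libraries farthest from the median score 128 genes passed, and 46 of them were among the 155.

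No list member passed along proliferation over all genes tested, and adjusted over the list alone only PSMA3, PSMA4 and PSMD12 of the proteasome did, with slopes of 0.52, 0.56 and 0.40. Camera at its preset correlation called 11 of 27 lists, and with an estimated correlation 0 of 27 passed. At the preset correlation MYC targets and the proteasome were called upward, with 12 of 14 and 22 of 30 positive slopes (adjusted p = 0.0158 and 0.0218, and 0.569 and 0.631 with the estimated one). Called downward at the preset correlation were NF-kappaB (adjusted p = 0.000598), interferon response and plasma cell identity (0.00357 for both), ribosomal proteins (0.00682), class II presentation (0.00706) and the BCL2 family (0.0122). Hypoxia and glycolysis (0.0136), stromal markers (0.0139) and immunotherapy antigens (0.0321) were called downward as well. Of the 14 plasma cell identity genes, 0 had a positive slope, with a median of -0.37. Positive slopes were 10 of 10 for granulocyte precursor and 10 of 10 for erythroid markers, with medians of 1.74 and 2.57. Neither list was called by camera (adjusted p = 0.750 and 0.267). Positive slopes were 9 of 14 for T and NK, 4 of 7 for B cell, 3 of 11 for monocyte, 2 of 8 for stromal and 0 of 6 for megakaryocyte markers. The score was not corrected for other cells. With the estimated correlation the adjusted p was 0.199 for NF-kappaB, plasma cell identity, the BCL2 family and hypoxia, and from 0.284 to 0.67 for the other 7. Median slope and test differed in sign for neosubstrates, cyclin D genes, immediate early genes, T and NK and B cell markers, none of them called.

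The file-name codes were compared as a technical check over the 16 libraries with a shared code. No gene differed among the 6 codes at an adjusted p of 0.05 in edgeR (0 of 21379), while 4026 had an unadjusted p under 0.05 and DESeq2's likelihood ratio test called 3429. Codes accounted for 76.7% of the variance of the monocyte score (permutation test, adjusted p = 0.0212), 78.1% of the granulocyte score (adjusted p = 0.0212), 73.6% of log2 total counts (adjusted p = 0.0215) and 71.9% of the number of genes detected (adjusted p = 0.0422), where 33.3% is expected by chance. The shares did not pass for the T and NK score (50.1%, adjusted p = 0.191), the erythroid score (56.1%, adjusted p = 0.139) or log2 CPM of CRBN (51.6%, adjusted p = 0.185). The share was 14.4% for the proliferation score (adjusted p = 0.873).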

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

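The alternative that left out the 2 libraries farthest from a covariate's median was chosen after seeing the data, and the others before. Of the counts recomputed, 52 stayed within 1.5 times, 12 were higher and 7 lower. Without a filter on low counts, 939 genes had more and 12 less spread than the trend in place of 0, 904 genes were associated with CRBN in place of 10, 1202 with proliferation in place of 155, and 376 differed among codes in place of 0. More genes were tested there, and the cause was not tested further. DESeq2 gave 509, 921 and 3429 for CRBN, proliferation and codes. Along CRBN, RLE gave 16, TMM without immunoglobulin genes 18 and filterByExpr 17, while 0 genes passed with the code term, without the library with the fewest counts, or without the 2 outermost libraries. The code term left 28 genes along proliferation, on fewer residual degrees of freedom, and without the 2 outermost libraries 128 passed, with 46 of the 155 among them. Estimated correlations took the lists called along CRBN from 4 to 0 and along proliferation from 11 to 0. Of the 21 relations, 7 passed without immunoglobulin genes and 0 after centring within codes, in place of 4. For all of these the cause was not tested. The count of lists that vary together stayed between 17 and 24, and that of pairs at 10 or 11.

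Gene pairs reversed only without division by gene length, which by construction favours long genes: IKZF3 minus IKZF1 became -1.70, BCL2 minus BCL2L1 0.16, TNFRSF17 minus FCRL5 -0.0494 and TNFRSF17 minus SLAMF7 -1.54. The other sign changes were in results that had not passed. Mean rho of cyclophosphamide metabolism became -0.0103 without immunoglobulin genes, -0.0240 without a filter, -0.000774 without the library with the fewest counts and -0.00798 with the authors' values. That of efflux transporters became -0.00621 with filterByExpr and -0.00557 without the library highest in other cell markers. The Spearman correlation of CRBN with IKZF1 became -0.0235 within codes, and with IKZF3 0.421 within codes and 0.00980 with the authors' values. The Spearman correlation of IKZF1 with IRF4 became -0.0760 with RLE, -0.0245 with filterByExpr and -0.0882 with the authors' values. The Spearman correlation of interferon with monocyte scores became 0.0559 within codes. The Spearman correlation of plasma cell identity with monocyte scores became -0.0122 with RLE, -0.0196 without a filter, -0.406 within codes, -0.0353 without the library with the fewest counts and -0.0221 with the authors' values. Over all alternatives, list values gained their call 6 times and lost it 11 times, relations 7 and 4, slopes of named genes along CRBN 52 and 31, and those along proliferation 4 and 44. Spread ratios of the ranked genes gained a call 25 times, each time without a filter on low counts. The median levels of PSMB5, ABCC1 and DDB1 moved by more than 1 SD on immunoglobulin-free library sizes, to 64.3, 66.6 and 266.8 CPM. The shallowest library held 26.5 M counts, and 17.8 M was the least outside immunoglobulin genes.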

Other observations

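The tests of 100 random orders of the libraries and of the covariates of the file-name codes were set before their results were seen, while the count at an unadjusted p and both light chain tests were chosen after. The antigens and survival genes held further contrasts in spread. GPRC5D ranged from 10.2 to 441.4 CPM with an SD of 1.36 log2 units, against 0.76 for TNFRSF17 and 0.76 for SLAMF7, in the same 17 libraries. BCL2 had an SD of 1.40, against 0.83 for MCL1 and 0.88 for BCL2L1. Of the drug target genes, DDB1 had an SD of 0.38, CRBN and IRF4 0.56 each, IKZF1 0.87, IKZF3 1.05 and NR3C1 1.17. These differences in spread were not tested.

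Chance could not be excluded for the genes associated with CRBN: counting the real order, 12 of 101 orders of the 17 libraries gave at least the 10 genes seen, and the highest of the other orders gave 158. An order that calls many times the real count can arise from a structure of the libraries, and no such structure was tested for. For the proliferation score, 1 of 101 orders, the real one, reached 155 genes and the highest other gave 54. This argues against a chance order without excluding it. The score's own genes varied together (mean rho 0.684), so further genes of the same programme were likely to pass in the real order. The test therefore says little about genes outside that programme.

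By file-name code, the adjusted threshold left chance undecided, since with 0 genes in the real split all 101 of 101 splits must give as many; the highest other gave 6. By unadjusted p under 0.05 there were 4026 genes in the real split and 2897 in the highest other, with 1 of 101 splits reaching the real count. As this count was chosen after the data were seen, it argues against chance without excluding it. An explanation by the content of other blood cells, which itself differed between codes, was tested with the mean other-cell score as a covariate: 3033 genes were left against 2757 in the highest other split, 1 of 101 reaching it. Depth and the number of genes detected as covariates left 3215 against 2290, again 1 of 101. An excess thus remained after each of these covariates as fitted. A mean over cell types cannot absorb each cell type on its own, and cell content and depth were not fitted together. Their part in the differences between codes therefore stays open. A batch of sample handling, library preparation or sequencing may lie behind the codes, but their meaning is not given, a difference between the tumours themselves stays open, and no biological explanation within the tumour cells was tested.

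The immunoglobulin kappa constant gene (chromosome 2, 89156674 to 89157196, GRCh37), singled out after its values were seen, held 1320 counts over all 17 libraries. That the kappa light chain was little expressed is argued against by its variable genes, which together reached 9536 CPM in the median library. A candidate explanation is that reads over overlapping gene models were left uncounted, since 6.69% of this gene's exonic bases are its own. It received 0.00546 counts per 100 counts of kappa variable genes, against 47.5 per 100 for the 6 lambda constant genes with more than 50% unique bases. A lambda constant gene with 0% unique bases held 0 counts over all 17 libraries, so the loss was not confined to kappa. Immunoglobulin shares of counts given above may therefore be lower bounds. Whether tumours with kappa or with lambda light chains lost more was not measured.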
